A study of Homo sapiens with 9 samples.

How the data were processed

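Total RNA of 9 libraries was sequenced: 3 of HEK293 Flp-In T-REx control cells, 3 of cells expressing a microRNA against CCDC97 and 3 of cells expressing a microRNA against TTC33. Each group was given tetracycline at 100 ng/ml for 3 days, and RNA was taken up with hot acid phenol, per the labels' protocols. The library kit, its strandedness and the sequences of the microRNAs are not given in the sources used here. Groups and replicate numbers were taken from the labels, which name no batch or day.

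The deposited values are whole-number counts of reads per gene, not normalized. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.39, aligned with HISAT2 (version not given in the sources used here) and counted with HTSeq 2.0.1 on the genome build GRCh38. The annotation release and the strand setting of the counting are not given in the sources used here. Each sample has a count table marked R12 and a smaller one marked U, whose meaning is not stated. The R12 counts were used throughout, and the sum of both was an alternative. The U counts were 6.55% to 11.9% of the sum. The rows of the tables that name no gene (no feature, ambiguous, low quality, not aligned, several alignments) held 33.4% to 57.9% of the R12 counts of a library and were left out of library sizes and tests. Gene symbols were taken from the count tables, which list 60664 genes, 20055 of them with a blank symbol.

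Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 18299, and libraries were scaled with TMM factors. A quasi-likelihood model with a term per group was fitted to all 9 libraries, so that the groups share an estimate of the spread with 6 residual degrees of freedom. The common biological coefficient of variation was 0.109. Contrasts were each knock-down against control and the TTC33 against the CCDC97 knock-down. The p-values are two-sided and Benjamini-Hochberg adjusted over the genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM stands for counts per 1e6 TMM-scaled library counts and is given as mean ± SD over 3 libraries. Per-library log2 values, including those by GC decile, are from log2 CPM with a prior count of 2. The median of a list in a comparison is over the edgeR log2 fold changes of its members. It can thus differ from the medians per library.

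Before the data were examined, 26 gene lists were fixed, of which 25 had at least 5 genes tested. They were tested with camera of limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01, two-sided and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Counts of members that rose or fell use the adjustment over all genes, and those marked as adjusted over the list alone use the p-values of the list's members only.

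The genes named in the text follow a rule also fixed before the data were examined. For each comparison with control they are the proteins of the network and the 6 genes that rose and the 6 that fell most among those past the threshold with a mean of at least 5 CPM and all knock-down libraries on one side of all control libraries. Chance alone puts 10% of unchanged genes on one side in this way. Added to these are up to 3 members with the smallest adjusted p of each list that passed or held at least 3 genes past the threshold. For the direct contrast the rule takes 4 genes each way. The result of 1 gene under this rule is not reported. REST and a list of 34 of its targets, 23 of them tested, were added after the rise of neuronal genes was seen. The target list was written from general knowledge, without the genes already seen to rise and before the values of its members or of REST were looked at. The single targets named, genes named as shared or opposite between the knock-downs beyond this rule, and UNC13A, U2AF1, DNAJC8 and IRF9 in the CCDC97 knock-down were chosen after their values were seen.

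Alternatives set before the data were examined were DESeq2 size factors and upper-quartile factors, no filter or a filter on a mean of 5 CPM, the DESeq2 1.42.0 Wald test, a fit of the 2 groups compared, the replicate number as a block, the sum of R12 and U counts, and leaving out each library in turn. A correction for GC content and transcript length was added after the data were seen. It subtracts smooth trends fitted per library with mgcv 1.9.3, using GC content and length from GENCODE release 29, which gave values for 18042 of the genes tested (98.6%). The release behind the deposited counts may differ from it. Coordinates are those of GENCODE release 29 on GRCh38.

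The overlap of both responses was compared with 20 simulated pairs of unchanged groups sharing the controls and with the overlap of independent lists. Sequences of 7 bases in 3' UTRs were tested for an association with log2 fold change by linear regression over 12476 protein-coding genes, with 3' UTR length, 3' UTR GC content and transcript GC content as covariates and Bonferroni adjustment over 16384 sequences. The longest annotated 3' UTR of each gene was used.

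The edgeR, DESeq2 and camera steps were tested on simulated data, in which 200 of 18299 genes and the members of a gene list were changed. These were negative binomial counts with the real mean levels and library sizes, and with the fitted dispersion of each gene shared by all groups. fry was not tested in this way. At folds of 1.5, 2, 4 and 8, edgeR recovered 40%, 70%, 92% and 96% of 50 genes each in the TTC33 comparison, with 2.34% of calls false. In the CCDC97 comparison it recovered 36%, 74%, 96% and 98%, with 4.95% false, and in the direct contrast 50%, 86%, 96% and 98%, with 4.12% false. With DESeq2, 6.01%, 14.9% and 6.5% of calls were false. The real groups differ in spread and GC trend, which the simulation leaves out, so these rates may not hold for the real data. The list, shifted by 1 on the log2 scale, was found in each comparison with 0 other lists past the threshold. For the sequence test the real fold changes were shuffled over genes and an effect was added for a random 7-base sequence, which ranked 1 at effects of -0.1 and -0.2 on the log2 scale with 0 unrelated sequences past the threshold. Scripts for sequences and plots used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.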

Results

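RNA was sequenced from HEK293 Flp-In T-REx cells, a modified human embryonic kidney line in which a transgene can be switched on with tetracycline. The 9 libraries fall into 3 groups of 3: cells expressing a microRNA against TTC33, cells expressing a microRNA against CCDC97, and control cells that express no microRNA. All groups received tetracycline at 100 ng/ml for 3 days. TTC33 gives its name to a protein assembly, the TTC33-associated network, that also holds PHF5A, a subunit of the SF3B splicing complex, and WDR61, a subunit of the SKI and PAF1 complexes. The question was how depletion of TTC33 or of CCDC97 changes gene expression.

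Counts assigned to genes came to 35262832, 36110891 and 31296393 in control replicates 1, 2 and 3. They came to 28366419, 31801574 and 21764203 in the CCDC97 knock-down, and to 30921816, 28082168 and 25846816 in the TTC33 knock-down. Between 26425 and 28814 genes had at least one count per library, and 18299 genes were tested. Every pair of replicates differed by more than sampling noise. Chi-square per degree of freedom was 3.59 to 6.31 between controls, 27.7 to 35.8 between CCDC97 knock-down replicates, and 32.3, 39.2 and 7.61 between TTC33 knock-down replicates, the last being replicates 2 and 3. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

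Replicate 1 of each knock-down stood apart from replicates 2 and 3 in how transcript levels followed the GC content of the genes. Against the control mean, genes of the lowest GC decile (median GC content 36.8%) had median log2 differences of -0.15, 0.17 and 0.16 in CCDC97 knock-down replicates 1, 2 and 3, and genes of the highest decile (63.8%) had 0.15, -0.28 and -0.28. In the TTC33 knock-down the values were 0.03, -0.44 and -0.48 for the lowest decile and -0.09, 0.36 and 0.39 for the highest. Across genes, which are not independent replicates, Spearman's correlation of the log2 fold change with GC content was 0.46 for the TTC33 knock-down and -0.21 for the CCDC97 knock-down.

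**Figure D1:**
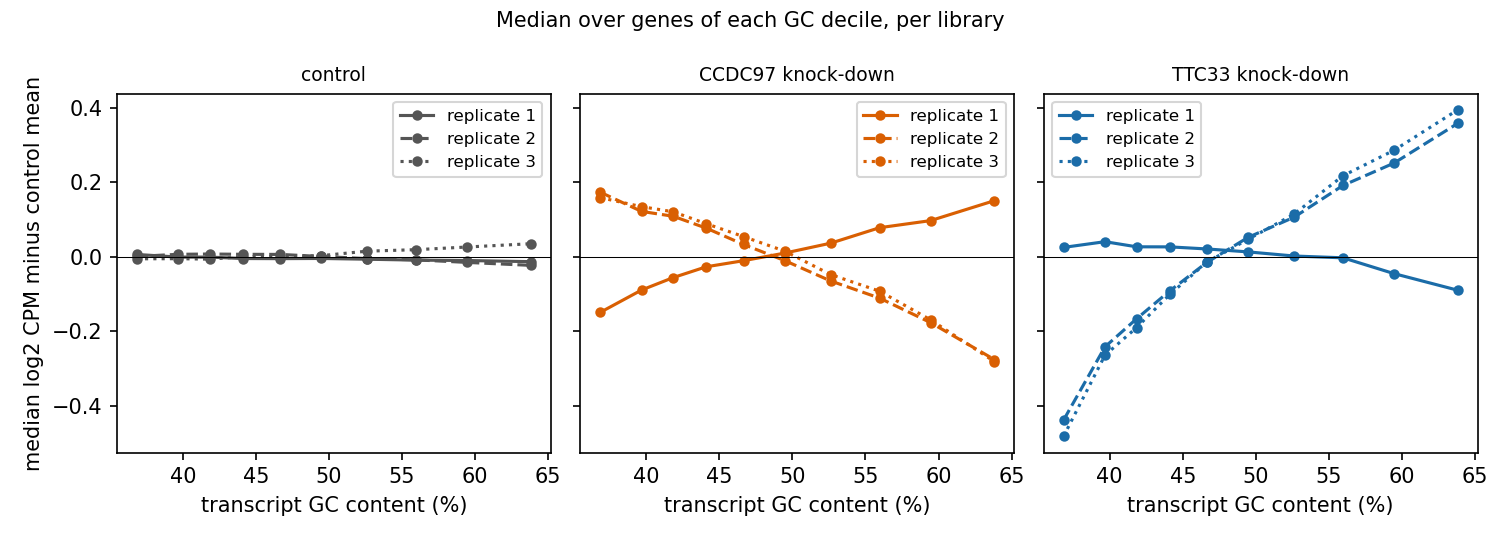
Median difference from the control mean (y axis, log2 CPM) of the genes in each decile of transcript GC content (x axis, %), with a line per library and a panel per group. Replicates 2 and 3 of the TTC33 knock-down reach 0.36 and 0.39 in the highest decile while replicate 1 lies at -0.09, and the CCDC97 knock-down replicates part the other way.

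Each microRNA lowered the mRNA it was directed against. TTC33 (ENSG00000113638; GRCh38 chromosome 5, 40512333 to 40755975, minus strand, 5 exons in the annotated coding transcript) went from 37.8 ± 0.77 CPM in controls to 7.41 ± 1.96 CPM in the TTC33 knock-down (SD, n = 3), with 9.67, 6.41 and 6.16 CPM in replicates 1, 2 and 3. Its log2 fold change was -2.34 ± 0.21 (SE; edgeR adjusted p = 0.000106), which leaves 19.7% of the control level. CCDC97 (ENSG00000142039; chromosome 19, 41310189 to 41324883, plus strand, 5 exons) went from 60.1 ± 0.55 to 15.6 ± 0.28 CPM in the CCDC97 knock-down, a log2 fold change of -1.94 ± 0.12 (SE; adjusted p = 1.24e-05), which leaves 26.0%. After the GC content and length correction the log2 fold changes of TTC33 and CCDC97 in their own knock-downs were -1.97 and -1.83. CCDC97 overlaps TGFB1 on the other strand without sharing annotated exon bases.

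CCDC97 mRNA rose in the TTC33 knock-down, to 80.7 ± 15.4 CPM (log2 fold change 0.43 ± 0.12, SE; edgeR adjusted p = 0.0371). This call was lost in 7 of the 9 fits that left out a library, with adjusted p up to 0.155 without TTC33 knock-down replicate 3, and the fold change was 0.27 there. It was 0.25 after the GC content and length correction. TTC33 mRNA in the CCDC97 knock-down did not pass (log2 fold change 0.19 ± 0.20, adjusted p = 0.632), with 30.0, 52.5 and 47.0 CPM in replicates 1, 2 and 3. The fold change was 0.40, 0.01 and 0.12 without CCDC97 knock-down replicate 1, 2 and 3, and 0.11 after the correction. PHF5A had log2 fold changes of 0.04 in both knock-downs, and WDR61 had -0.11 in the TTC33 knock-down and 0.18 in the CCDC97 knock-down, with adjusted p of 0.729, 0.805, 0.42 and 0.277. WDR61 in the CCDC97 knock-down had 0.08 without replicate 2 of that group, and PHF5A ranged from 0.01 to 0.05 and from 0.01 to 0.07 without a library. WDR61 in the TTC33 knock-down and PHF5A in the CCDC97 knock-down changed sign, to 0.03 and -0.04, when GC content and gene length were corrected for.

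**Figure D2:**
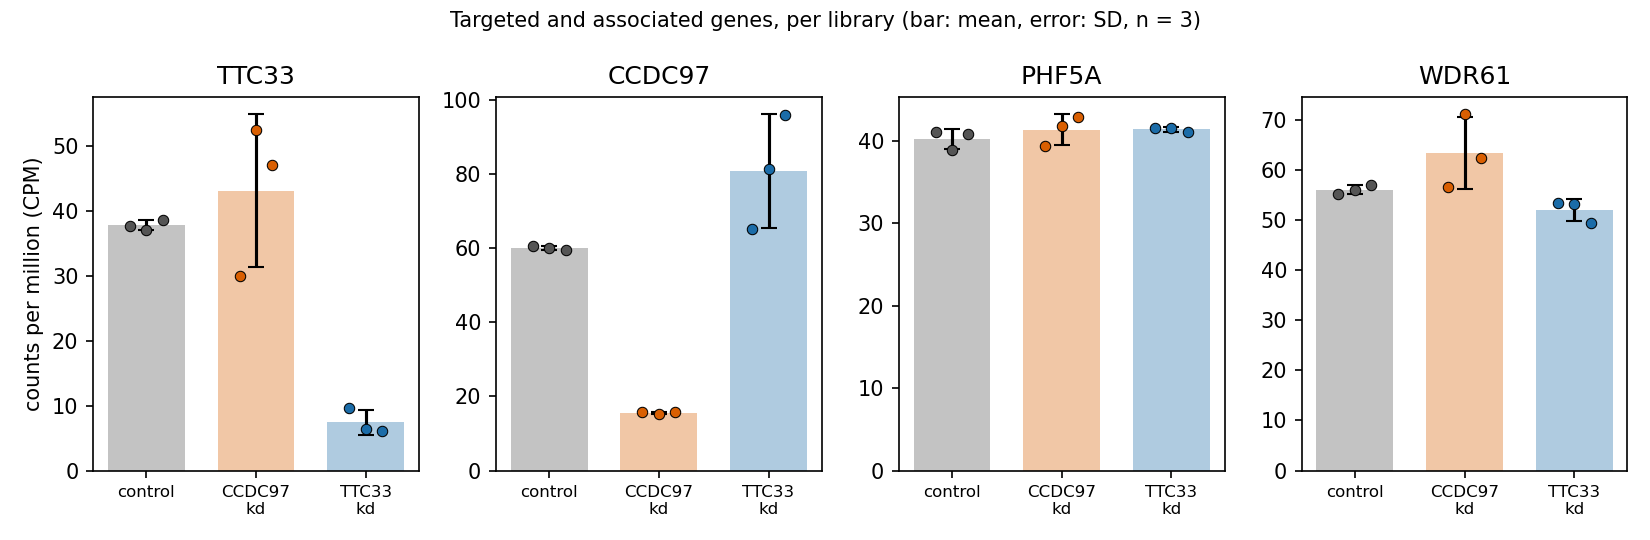
CPM (y axis, from 0) of TTC33, CCDC97, PHF5A and WDR61 in controls, the CCDC97 knock-down and the TTC33 knock-down (kd), with a point per library, bars at the mean and error bars of 1 SD (n = 3). TTC33 falls from 37.8 to 7.41 CPM and CCDC97 from 60.1 to 15.6 CPM in their own knock-downs.

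Among genes with a mean of at least 5 CPM, those that rose most in the TTC33 knock-down included genes known from neurons. UNC13A, which primes synaptic vesicles for release, rose 12.4-fold, from 2.18 ± 0.17 to 27.2 ± 1.51 CPM (SD, n = 3; log2 fold change 3.64 ± 0.12, SE; edgeR adjusted p = 6.24e-08). CPLX2, a complexin that acts on vesicle fusion, rose 11.7-fold (log2 3.55 ± 0.17). The granule proteins SCG3 and CHGB rose 9.36-fold (3.23 ± 0.15) and 5.71-fold (2.51 ± 0.19). The non-coding RNA LINC00632 rose from 14.6 ± 1.13 to 122 ± 13.5 CPM (3.07 ± 0.10). The membrane metalloproteinase gene MMP24 rose by 2.94 ± 0.15 on the log2 scale. Below TTC33 itself, the genes with the largest fall at this level of expression were FAM3C, which encodes a secreted protein (log2 fold change -1.73 ± 0.11, from 94.6 ± 0.48 to 28.4 ± 3.36 CPM), TMEM19 (-1.39 ± 0.11), MDFIC (-1.36 ± 0.22), AMOT, a scaffold protein of the Hippo pathway (-1.35 ± 0.07, from 403 ± 3.66 to 158 ± 9.02 CPM), and ZNF853 (-1.35 ± 0.16).

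In all, 2186 of the 18299 genes passed an adjusted p of 0.05 in the TTC33 knock-down, 1190 higher and 996 lower, with a median absolute log2 fold change of 0.51. Of the genes named by rule, the 6 that rose most and the 5 that fell most beside TTC33 passed in each of the 9 fits that left out a library. Correcting for GC content and length raised the count to 5142, among them 2084 of the 2186, and testing without a filter on low counts raised it to 3821. With the replicate number as a block the count was 756. The count was 552, 570 or 686 without control replicate 1, 2 or 3, and 6512, 650 or 700 without TTC33 knock-down replicate 1, 2 or 3. LINC00632 shares 789 exon bases with CDR1 and MMP24 shares 799 with MMP24OS on the other strand, and reads there cannot be told apart without strand. The longest annotated 3' UTRs of FAM3C and MDFIC each held 2 copies of the sequence AGCTATA and that of TMEM19 held 1, while those of AMOT and ZNF853 held none. Among genes with 3' UTRs of like length, 5.98%, 14.8% and 18.6% held the site for FAM3C, MDFIC and TMEM19. GATGAAA, the next sequence by p, had 4 copies in MDFIC, 2 in ZNF853, 1 in TMEM19 and none in FAM3C and AMOT. Of genes with 3' UTRs of like length 30.8%, 13.3% and 34.6% held it for the first 3.

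Of the 25 gene lists tested, all fixed before the data were examined, 7 passed in the TTC33 knock-down and all 7 were shifted upwards. After the GC content and length correction 12 passed, 8 upwards and 4 downwards. Genes of the G2 and M phases passed only then, upwards (median log2 fold change 0.02 before and 0.11 after, camera adjusted p = 0.00916 after). Downwards, and also only then, passed targets of ATF4 (-0.10 and -0.16, adjusted p = 0.0037), cholesterol genes (-0.07 and -0.06, adjusted p = 0.0198), hypoxia and glycolysis genes (-0.08 and -0.14, adjusted p = 0.00991) and replication-dependent histones (just above 0 and -0.11, adjusted p = 0.0415). None of these 5 passed with an estimated correlation. Neuronal genes had the lowest p: 14 of 25 rose and 1 fell, with a median log2 fold change of 0.77 (camera adjusted p = 1.18e-10), and 17 rose and 1 fell when adjusted over the list alone. The medians per library were 0.65, 0.73 and 0.59 in the TTC33 knock-down and 0.09, 0.12 and -0.07 in the CCDC97 knock-down. SYP, an integral protein of synaptic vesicles, rose from 13.5 ± 1.17 to 63.3 ± 7.88 CPM (log2 fold change 2.23 ± 0.12), and CHGA, a granule protein, rose 9.02-fold (3.17 ± 0.17). SYP shares 68 exon bases with SYP-AS1 on the other strand. Without the correction this was the only list that held with an estimated correlation between genes (adjusted p = 0.00627).

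Immediate early genes, which respond within minutes to growth signals and stress, also rose in the TTC33 knock-down. Of 32 tested, 12 rose and 1 fell (median log2 fold change 0.35, camera adjusted p = 6.87e-07; adjusted over the list alone, 22 and 3), with an adjusted p = 0.337 with an estimated correlation, and adjusted p = 0.0412 when that was run on corrected values. The transcription factors EGR1, FOSB and KLF4 rose by 1.33 ± 0.14, 1.26 ± 0.16 and 0.71 ± 0.10 on the log2 scale. Clustered protocadherins, cell adhesion genes of neurons that share exons and reads within each cluster, had 8 of 26 higher and none lower (median 0.38, adjusted p = 6.87e-07; adjusted over the list alone, 9; adjusted p = 0.069 with an estimated correlation). PCDHA11 rose by 1.88 ± 0.18 and PCDHB2 by 1.63 ± 0.16, both from about 1 CPM or less in controls.

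The other 4 lists that passed without the correction included stress responses. Of 22 genes of the unfolded protein response, 5 rose (11 adjusted over the list alone; median log2 fold change 0.20, camera adjusted p = 0.0067; adjusted p = 0.125 with an estimated correlation), including MANF, a secreted stress protein of the endoplasmic reticulum, by 0.51 ± 0.09. Of 29 p53 targets, 7 rose and 2 fell (11 and 3 adjusted over the list alone; adjusted p = 0.0363; adjusted p = 0.169 with an estimated correlation). The cell cycle inhibitor CDKN1A and the apoptosis effector BAX rose by 0.60 ± 0.09 and 0.52 ± 0.09, and the stress sensor SESN1 fell by 0.57 on the log2 scale. Of 20 heat shock genes, 5 rose (10 adjusted over the list alone; adjusted p = 0.022; adjusted p = 0.688 with an estimated correlation), among them HSPA8, which has processed copies that can take its reads, by 0.38 ± 0.09. The calls of HSPA8, HSPH1 and BAG3 were each lost in 5 of the 9 fits that left out a library, and HSPH1 went from 0.31 to 0.49 with the correction. Of 13 mitochondrially encoded mRNAs, 6 rose (7 adjusted over the list alone; median 0.36, adjusted p = 0.000195; adjusted p = 0.529 with an estimated correlation), with MT-ND2, a complex I subunit, up by 0.70 ± 0.11. Leaving out a library ended the call of the p53 list in 3 of 9 fits (adjusted p up to 0.249), of the heat shock list in 2 (up to 0.0638) and of the unfolded protein response list in 1 (0.0575). Without TTC33 knock-down replicate 1, 4 lists passed in place of 7.

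Several lists that did not pass as a whole without the correction held genes that moved in the TTC33 knock-down. Among targets of ATF4, 4 rose and 9 fell (8 and 11 adjusted over the list alone; list adjusted p = 0.288). PPP1R15A, a phosphatase subunit that ends the stress response, rose by 0.82 ± 0.10, and DDIT4, an inhibitor of mTORC1, fell by 0.66 on the log2 scale. Among cholesterol genes 1 rose and 5 fell, both over all genes and adjusted over the list alone (list adjusted p = 0.477). INSIG1, which holds back the pathway's transcription factors, fell by 0.66. Of the epithelial genes 1 rose and 2 fell, both over all genes and adjusted over the list alone (list adjusted p = 0.71). ST14 rose by 1.02 and EPCAM fell by 0.29, each lost in 6 of 9 fits. CDH1, the epithelial cadherin, fell from 10.8 ± 1.30 to 4.85 ± 0.87 CPM (log2 fold change -1.15 ± 0.14), and IFI16, an interferon-induced DNA sensor, rose from 0.14 ± 0.10 to 1.75 ± 0.09 CPM. Of the interferon-stimulated genes 3 rose and 3 fell (6 and 6 adjusted over the list alone; list adjusted p = 0.587). Of the mesenchymal and matrix genes 6 rose and 1 fell (7 and 4 adjusted over the list alone; list adjusted p = 0.355), with THBS1 up by 0.85 ± 0.14. Of 13 microRNA biogenesis and Argonaute genes 1 rose and 2 fell (2 and 3 adjusted over the list alone, list camera adjusted p = 0.587). Among them the microRNA effector gene AGO4 fell by 0.41 on the log2 scale. Cytosolic ribosomal proteins (list adjusted p = 0.355), the SKI complex and RNA exosome (0.71), the PAF1 complex (0.71), and the U2 snRNP and SF3 complexes (0.477) did not pass. In the last, 2 rose and 1 fell, also adjusted over the list alone. The splice site factor U2AF1 fell by 0.47 (lost in 4 of 9 fits), and SF3B4 and SUGP1 each rose by 0.42 (lost in 7 and 6). SF3B4 rose by 0.28 without TTC33 knock-down replicate 3. Neither did genes of the G2 and M phases, where the test pointed up and the mean was -0.01, and replication-dependent histones, where the test pointed down with a mean of -0.02 and a median just above 0.

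In the CCDC97 knock-down the genes that rose most, among those with a mean of at least 5 CPM, were in part also higher with TTC33 depleted. COL5A2, a fibrillar collagen chain, rose 3.53-fold from 5.19 ± 0.16 to 18.3 ± 0.34 CPM (SD, n = 3; log2 fold change 1.82 ± 0.10, SE; edgeR adjusted p = 5.16e-06), and DDR2, a collagen receptor kinase, rose 2.89-fold (1.53 ± 0.14). FAM71E1 (2.17 ± 0.17), the monocarboxylate transporter gene SLC16A7 (2.02 ± 0.33), the homeobox gene HOXC11 (1.56 ± 0.08) and MIR222HG, the host transcript of the microRNAs miR-221 and miR-222 (1.54 ± 0.21), rose as well. CEBPE, a myeloid transcription factor, fell from 47.6 ± 1.89 to 9.0 ± 1.81 CPM (-2.41 ± 0.18), and CYB5R3, a cytochrome b5 reductase, fell from 133 ± 6.33 to 25.5 ± 4.53 CPM (-2.38 ± 0.18). The adhesion genes PCDH19 and TENM1 and the replication gene DONSON fell by 1.42, 1.41 and 1.38 on the log2 scale. FAM71E1, SLC16A7, COL5A2 and HOXC11 also rose in the TTC33 knock-down, by 0.71, 1.68, 0.46 and 0.59, of which the first 3 lost the call in 5, 1 and 4 of the 9 fits that left out a library. DONSON also fell there, by 0.45, while TENM1 rose by 0.58.

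In all, 835 of the 18299 genes passed in the CCDC97 knock-down, 379 higher and 456 lower, with a median absolute log2 fold change of 0.51. The 6 genes that rose most and the 5 that fell most beside CCDC97 passed in each of the 9 fits that left out a library. Correcting for GC content and length gave 3527 genes, 1985 higher and 1542 lower, among them 820 of the 835. DESeq2 called 1447, a fit of the 2 groups alone 1339, and a test without a filter on low counts 1369, while a fit with the replicate number as a block called 240. The count was 203, 219 or 241 without control replicate 1, 2 or 3, 1860, 256 or 330 without CCDC97 knock-down replicate 1, 2 or 3, and 1981 without TTC33 knock-down replicate 1, which shares the estimate of the spread. On the other strand, FAM71E1 shares 324 exon bases with EMC10, DONSON 307 with SON and TENM1 241 with STAG2, and HOXC11 overlaps HOTAIR without sharing any. The longest annotated 3' UTRs of CYB5R3, PCDH19 and DONSON each held 1 copy of the sequence GAGCAGA, and those of CEBPE and TENM1 held none. Of genes with 3' UTRs of like length 19.5%, 34.9% and 17.5% held it for CYB5R3, PCDH19 and DONSON.

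Of the lists, 11 passed in the CCDC97 knock-down, all shifted upwards. Cytosolic ribosomal proteins and replication-dependent histones had the lowest p, although most of their members did not pass over all genes tested. Of 78 cytosolic ribosomal protein genes, 24 rose and none fell, and 59 rose when adjusted over the list alone (median log2 fold change 0.29, camera adjusted p = 2.39e-21; adjusted p = 0.365 with an estimated correlation). RPSA rose by 0.56 ± 0.07, from 763 ± 18.8 to 1124 ± 104 CPM, and RPL15 by 0.43 ± 0.07. Of 40 replication-dependent histone genes, 11 rose and none fell, and 27 rose and 1 fell when adjusted over the list alone (median 0.34, adjusted p = 7.63e-12; adjusted p = 0.365 with an estimated correlation). The linker histone gene H1-3 rose by 0.98 ± 0.09 and the core histone gene H2AC8 by 0.65 ± 0.09. Ribosomal protein genes have many processed pseudogenes and histone genes near-identical copies, so counts of single members are uncertain.

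Lists of respiratory chain mRNAs passed too in the CCDC97 knock-down. Of 13 mitochondrially encoded mRNAs, 8 rose (11 adjusted over the list alone; median log2 fold change 0.36, camera adjusted p = 1.64e-07; adjusted p = 0.365 with an estimated correlation), with MT-ND1 up by 0.63 ± 0.11, a call lost in 3 of the 9 fits that left out a library. After the GC content and length correction the median was 0.23, 5 rose, and the adjusted p = 0.0125. Mitochondrial ribosomal RNA took 1.54% of the counts in CCDC97 knock-down replicate 3 and at most 0.388% in every other library. Of 72 nuclear-encoded respiratory chain genes, 8 rose and 1 fell (23 and 1 adjusted over the list alone; adjusted p = 3.07e-07; adjusted p = 0.38 with an estimated correlation). NDUFS4, a complex I subunit, rose by 0.53 ± 0.11 and NDUFV3, another, fell by 0.44, with calls lost in 5 and 2 of the 9 fits. The median of the nuclear-encoded list went from 0.20 to 0.11 without CCDC97 knock-down replicate 2.

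A further 7 lists passed in the CCDC97 knock-down with few single genes past the threshold. Of 39 genes of the G2 and M phases 3 rose (11 adjusted over the list alone; adjusted p = 1.82e-06; adjusted p = 0.38 with an estimated correlation), led by the kinase-binding gene CKS2 (0.55 ± 0.11, lost in 4 of 9 fits). Of 29 p53 targets 2 rose (5 adjusted over the list alone; adjusted p = 0.000296; adjusted p = 0.103 with an estimated correlation), the receptor gene EDA2R by 0.62 ± 0.10 and CDKN1A by 0.55 ± 0.09, the latter lost in 2 of 9 fits. Of 20 heat shock genes 2 rose (4 adjusted over the list alone; adjusted p = 0.00218; adjusted p = 0.38 with an estimated correlation), DNAJA1 and HSP90AA1, each lost in 7 of 9 fits. Of 26 clustered protocadherins, PCDHB2 alone rose, also when adjusted over the list alone (1.28 ± 0.17; list adjusted p = 0.00661; adjusted p = 0.365 with an estimated correlation). Of 24 mesenchymal and matrix genes 4 rose and 1 fell (5 and 3 adjusted over the list alone; adjusted p = 0.0383; adjusted p = 0.38 with an estimated correlation), with the collagen gene COL3A1 up by 1.11 ± 0.16 and the matrix protein gene THBS1 by 1.02 ± 0.14. The SKI complex and RNA exosome list (adjusted p = 0.0196; adjusted p = 0.424 with an estimated correlation) held a rise of the exosome subunit gene EXOSC7 by 0.61 ± 0.08 and a fall of EXOSC6 by 0.33, lost in 5 of 9 fits, and 5 rose and 1 fell when adjusted over the list alone. Among 18 non-coding hosts of snoRNAs SNHG6 rose and SNHG3 fell, lost in 4 and 5 of 9 fits, and 3 rose and 1 fell when adjusted over the list alone (adjusted p = 0.0179; adjusted p = 0.38 with an estimated correlation). After the GC content and length correction 9 of the 11 lists passed. The SKI complex and RNA exosome went from a median of 0.15 to 0.10 (adjusted p = 0.0635) and the snoRNA hosts from 0.14 to 0.12 (adjusted p = 0.0931). SNHG6 went from 0.41 to 0.24. Leaving out a library ended the call of the SKI complex and RNA exosome in 2 of 9 fits (adjusted p up to 0.102), of snoRNA hosts in 1 (0.0703) and of matrix genes in 1 (0.401). Without CCDC97 knock-down replicate 2 the medians of these 3 lists were 0.07, 0.08 and 0.14, the last from 0.06. Those of the G2 and M phases and of protocadherins went from 0.17 to 0.11 and from 0.20 to 0.12. Without CCDC97 knock-down replicate 1 the SKI complex and RNA exosome had 0.25 and the G2 and M phases 0.27, and without control replicate 3 matrix genes had 0.03.

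Neuronal genes did not pass as a list in the CCDC97 knock-down (median log2 fold change 0.07, adjusted p = 0.389), where UNC13A alone rose over all genes tested (0.70 ± 0.13, lost in 4 of 9 fits) and 3 rose and 2 fell when adjusted over the list alone. In glycolysis and hypoxia genes, 1 rose and 5 fell (5 and 6 adjusted over the list alone; list adjusted p = 0.963), and the phosphofructokinase gene PFKP fell from 185 ± 7.64 to 72.5 ± 8.38 CPM (-1.35 ± 0.12). The median of that list and of the S phase list lay just above 0, while their means were -0.03 and -0.04 and their tests pointed down. Of 31 interferon-stimulated genes 2 rose and 2 fell (3 and 3 adjusted over the list alone; list adjusted p = 0.245), and the test and the median of 0.12 pointed up. SAMD9 and IFITM3 rose by 0.74 and 0.89, lost in 5 and 7 of 9 fits, while STAT2, which carries interferon signals, and its partner IRF9 fell by 0.50 and 0.84, the latter lost in 7. The PAF1 complex (adjusted p = 0.203) and the U2 snRNP and SF3 complexes (0.245) did not pass. In the latter U2AF1 fell by 0.76 ± 0.10 (adjusted p = 0.0024), as it did in the TTC33 knock-down, and DNAJC8 rose by 0.33, lost in 7 of 9 fits. Adjusted over the list alone 2 rose and 1 fell.

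**Figure D3:**
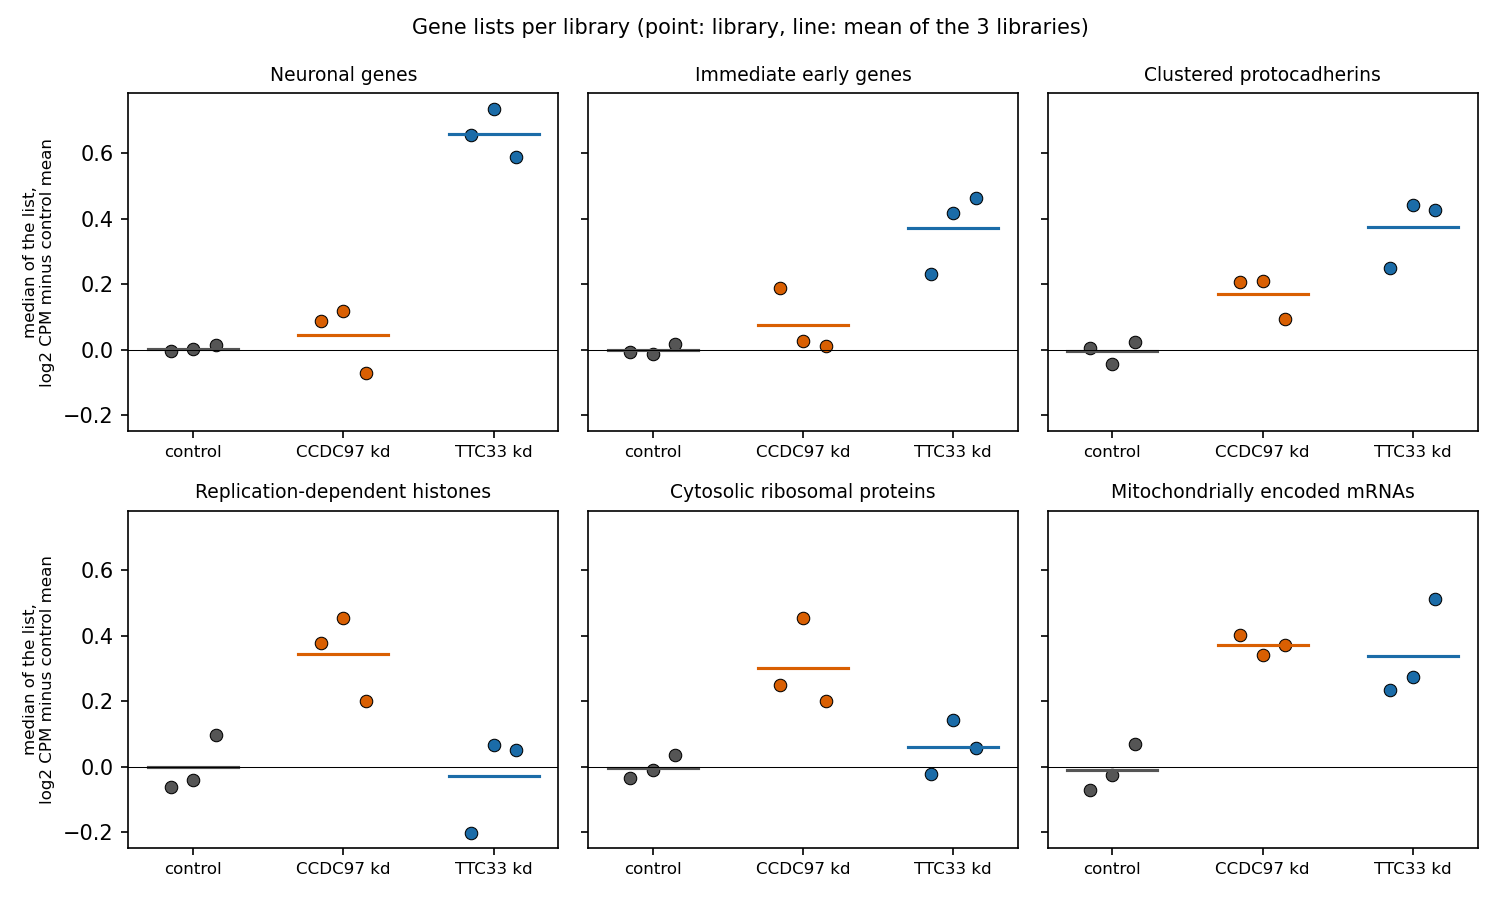
Median over each gene list of the difference from the control mean (y axis, log2 CPM) in controls, the CCDC97 knock-down and the TTC33 knock-down (kd), with a point per library and a line at the mean of 3 libraries. Neuronal genes lie at 0.59 to 0.73 in the TTC33 knock-down, and ribosomal protein genes at 0.20 to 0.45 in the CCDC97 knock-down.

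Some genes moved together in both knock-downs. AMOT fell by 1.35 with TTC33 depleted and by 1.27 with CCDC97 depleted, and SLC16A7 rose by 1.68 and 2.02. SAMD9, an interferon-induced antiviral gene, rose by 0.77 and 0.74 on the log2 scale, the latter lost in 5 of the 9 fits that left out a library. In all, 90 genes were higher and 106 lower in both, 23.5% of the CCDC97 calls. Independent lists of these sizes would share 24.6 and 24.8. Unchanged groups simulated against the same controls shared 0.05 and 0 on average over 20 runs, but such groups hold no real effects to share, so this does not show how many of the 196 come from the shared controls. In opposite directions 31 genes were called, against 50.3 for independent lists and 0 in the simulation. Across the 18299 genes, which are not independent replicates, the fold changes correlated with r = 0.337 and shared their sign in 55.6% of genes. Simulated unchanged groups that shared simulated controls gave a mean r of 0.47 (0.45 to 0.491) and 66.0%. The covariance was 0.0509 against a simulated 0.0248, a difference of 0.0261. The simulation gave controls and knock-downs the same dispersion per gene and no GC trend. Real controls varied less (chi-square per degree of freedom 3.59 to 6.31) than most knock-down pairs (27.7 to 39.2, and 7.61 for TTC33 knock-down replicates 2 and 3). The simulated r and covariance may thus be too high, and they cannot tell how much of the observed values comes from the shared controls. With 3 control libraries the controls could not be split into parts of at least 2, so part of the excess in shared calls and covariance may come from the shared controls. The controls express no microRNA, so an effect of expressing any microRNA cannot be told apart from a shared effect of depletion. Nor can any other difference between the control cells and the microRNA-expressing lines. The shared count of 196 was 39, 36 or 42 without control replicate 1, 2 or 3, 314, 86 or 92 without CCDC97 knock-down replicate 1, 2 or 3, and 594, 77 or 80 without TTC33 knock-down replicate 1, 2 or 3. It was 346 without a filter on low counts, 335 with DESeq2, 48 with the replicate number as a block and 1327 after the GC content and length correction.

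**Figure D4:**
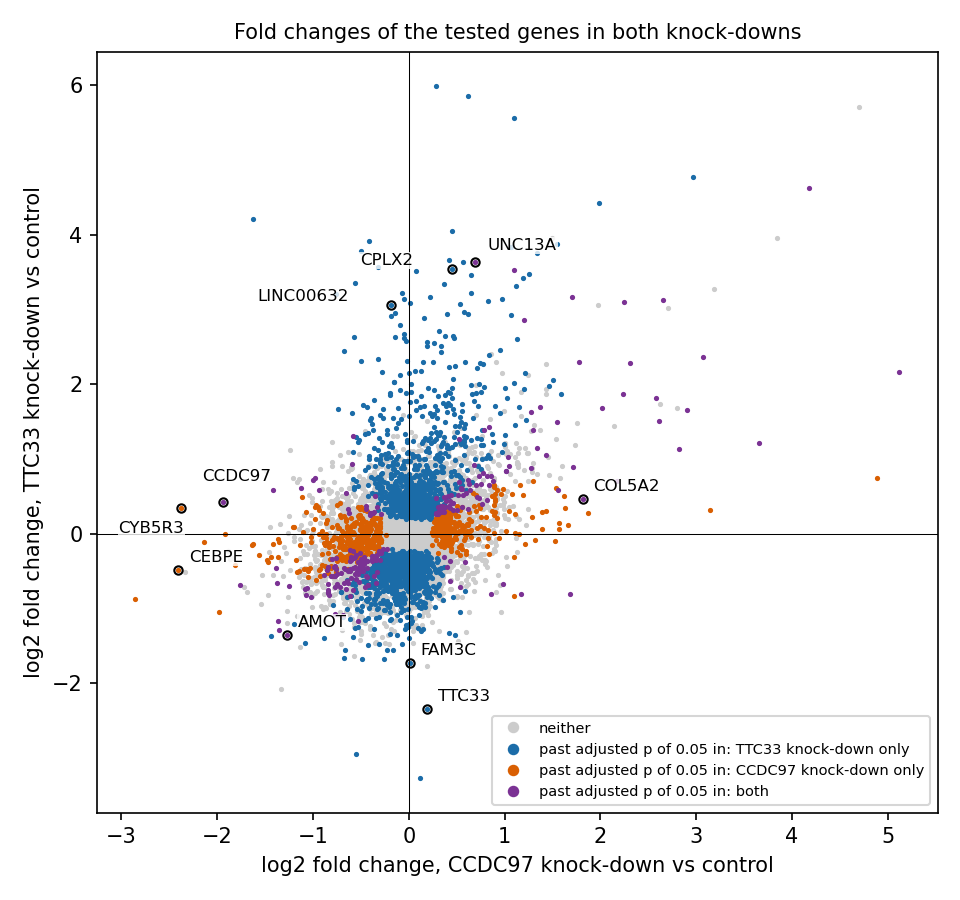
Log2 fold change against control of the 18299 tested genes in the CCDC97 knock-down (x axis) and the TTC33 knock-down (y axis), with a point per gene coloured by where it passed an adjusted p of 0.05. UNC13A, CPLX2 and LINC00632 lie above 3 on the y axis, and CEBPE and CYB5R3 below -2 on the x axis.

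Compared directly, and among genes with a mean of at least 5 CPM, LINC00632, CPLX2 and UNC13A were higher in the TTC33 knock-down than in the CCDC97 knock-down by 3.26 ± 0.10, 3.10 ± 0.16 and 2.94 ± 0.12 (log2, SE), and CYB5R3 by 2.73 ± 0.18, at 169 ± 42.8 against 25.5 ± 4.53 CPM (SD, n = 3). Beside TTC33 (-2.53 ± 0.22), the lowest at this level of expression were ZNF853 (-1.83 ± 0.16), IL6ST, the shared receptor chain of interleukin-6 cytokines (-1.75 ± 0.15, at 69.8 ± 15.7 against 235 ± 33.7 CPM), and FAM3C (-1.75 ± 0.11). All 8 passed in each of the 9 fits that left out a library. The 31 genes called in opposite directions against control, which were thereby chosen for a difference between the knock-downs, included TENM1 (2.00, as the log2 difference TTC33 minus CCDC97 knock-down), the G protein gene GNAO1 (1.89), H1-3 (-1.65) and the actin-binding protein gene FLNC (-1.98). Against control the call of GNAO1 in the CCDC97 knock-down was lost in 7 of the 9 fits and that of FLNC in the TTC33 knock-down in 5.

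Of the 25 lists, 9 passed the direct contrast, 3 higher and 6 lower in the TTC33 knock-down. Neuronal genes were higher (15 of 25 higher and 3 lower, 17 and 3 adjusted over the list alone; median log2 difference 0.60, camera adjusted p = 1.34e-07), and this list alone held with an estimated correlation (adjusted p = 0.0187). Immediate early genes (13 higher, 2 lower, also adjusted over the list alone; adjusted p = 0.000657; adjusted p = 0.566 with an estimated correlation) and clustered protocadherins (6 higher, also adjusted over the list alone; adjusted p = 0.00305; adjusted p = 0.489 with an estimated correlation) were higher. Replication-dependent histones were lower (2 higher, 24 lower of 40, 28 lower adjusted over the list alone; median -0.41, adjusted p = 6.78e-08; adjusted p = 0.566 with an estimated correlation), as were ribosomal proteins (1 higher, 36 lower of 78, 42 lower adjusted over the list alone; median -0.24, adjusted p = 1.99e-09; adjusted p = 0.702 with an estimated correlation). Genes of the G2 and M phases (13 lower, 14 adjusted over the list alone; adjusted p = 0.00263; adjusted p = 0.722 with an estimated correlation) and respiratory chain genes (2 higher, 13 lower, also adjusted over the list alone; adjusted p = 0.00263; adjusted p = 0.766 with an estimated correlation) were lower. So were the SKI complex and RNA exosome (3 higher, 7 lower, 4 and 10 adjusted over the list alone; adjusted p = 0.036; adjusted p = 0.722 with an estimated correlation) and non-coding snoRNA hosts (5 lower, 6 adjusted over the list alone; adjusted p = 0.036; adjusted p = 0.566 with an estimated correlation). After the GC content and length correction 7 lists passed, and 4 of the 9 did not. The median of genes of the G2 and M phases went from -0.23 to -0.04 (adjusted p = 0.23). That of the SKI complex and RNA exosome went from -0.23 to -0.03 (adjusted p = 0.603), of clustered protocadherins from 0.27 to 0.08 (adjusted p = 0.168) and of snoRNA hosts from -0.17 to -0.13 (adjusted p = 0.0604). Respiratory chain genes went from -0.15 to -0.09 (adjusted p = 0.0124) and immediate early genes from 0.27 to 0.18 (adjusted p = 0.00752). Targets of ATF4, downwards (median -0.21, adjusted p = 0.000189), and the unfolded protein response, upwards (0.16, adjusted p = 0.0244), passed only with the correction. Leaving out a library ended the call of the SKI complex and RNA exosome in 4 of 9 fits, of snoRNA hosts in 3 and of respiratory chain genes in 2. Without CCDC97 knock-down replicate 2 the median of respiratory chain genes was -0.06 (adjusted p = 0.0801) and that of ribosomal proteins -0.16, and without TTC33 knock-down replicate 2 that of protocadherins was 0.15. Among lists that did not pass without the correction, test, median and mean differed in sign for p53 targets, interferon-stimulated genes, cholesterol genes, hypoxia genes, microRNA genes, matrix genes, heat shock genes, mitochondrial mRNAs, abundant non-coding RNAs, and the U2 snRNP and SF3 complexes.

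In all, 3943 genes differed between the knock-downs, 2072 higher and 1871 lower in the TTC33 knock-down. Spearman's correlation of the log2 difference with GC content was 0.558 across genes, and 2986 of the 3943 genes were among the 5115 called after the GC content and length correction. The count was 6192, 1528 or 1830 without CCDC97 knock-down replicate 1, 2 or 3, 7767, 1605 or 1624 without TTC33 knock-down replicate 1, 2 or 3, and 1479 in a fit of the 2 groups alone. With the replicate number as a block it was 1857.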

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

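The GC content and length correction, the comparison of target depletion between replicates and the tests on REST were chosen after the data were seen, although the outcome of each REST test was predicted before it was run.

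Reads with several alignments, which enter no gene count, took a larger share in most knock-down libraries than in any control, where the highest share was 18.2%. The shares were 19.3% and 37.6% in CCDC97 knock-down replicates 1 and 3, and 21.8%, 22.1% and 29.03% in TTC33 knock-down replicates 1, 2 and 3. CCDC97 knock-down replicate 2, at 8.43%, lay below all controls.

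Neuronal genes differed between the knock-downs, with a median log2 difference of 0.60, and so did REST, the repressor that keeps neuronal genes silent outside neurons, at -0.82 (adjusted p = 0.00172). In the TTC33 knock-down the corrected median of the list was 0.73 against 0.77 before, and the list still passed with an estimated correlation (adjusted p = 0.0104), which argues against the GC trend as the whole cause. REST mRNA fell from 96.9 ± 1.04 to 59.9 ± 9.59 CPM (mean ± SD of 3 libraries; edgeR log2 fold change -0.69 ± 0.12, adjusted p = 0.00601), and of 23 REST targets outside the list, written down from general knowledge before their values were seen, 17 rose and none fell, with a median of 1.08 (limma camera on this list alone with an estimated correlation, a p of 0.00249). A partial release of REST-repressed genes stays a hypothesis. These targets include neuronal genes such as BSN, and no neuronal genes outside REST control were compared with them. Their rise therefore cannot be told apart from a general rise of neuronal genes. SCG2, CALB1 and CDK5R2 had means of only 0.36, 0.37 and 0.89 CPM over all libraries. The same targets had a median of -0.05 in the CCDC97 knock-down (limma camera with an estimated correlation, a p of 0.846). The longest 3' UTR of REST holds 0 of the 2 leading sequences associated with lower mRNA in these cells, which argues against direct repression of REST through them, and an effect of the cell line or of the microRNA apart from TTC33 stays open because each target has a single microRNA line.

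Replicate 1 of each knock-down stood apart from replicates 2 and 3, and in opposite directions: the deviations of both from their group means correlated with r = -0.504 across genes. After the GC content and length correction the correlation was -0.193, so a GC-dependent step of library making may explain most of it, while the remainder is unexplained. CCDC97 mRNA in replicate 1 was 1.02 times the mean of replicates 2 and 3, which argues against a difference in depletion as a common cause, although the TTC33 ratio was 1.54. Both ratios are of CPM without the correction, under which the log2 fold change of TTC33 went from -2.34 to -1.97. The labels name no batch, so no within-batch value can be had, and no biological explanation other than depletion was tested.

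Genes called in opposite directions against control numbered 31, and their difference in the direct contrast follows from that choice. They included TENM1, GNAO1, GRIK3 and RPS6KA4, higher with TTC33 depleted and lower with CCDC97 depleted, and H1-3 and FLNC, the other way. Leaving out a library ended the call of GNAO1 in the CCDC97 knock-down in 7 of 9 fits, and in the TTC33 knock-down that of RPS6KA4 in 7 (log2 fold change 0.62, and 0.37 after the GC content and length correction) and of FLNC in 5.

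Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. In the TTC33 comparison 1 split, the real one, gave as many as 2186 genes and the highest of the others gave 0. In the CCDC97 comparison it was again 1 split, with 835 genes and 0 for the highest other. In the direct contrast 2 splits gave as many as the real 3943. The other put CCDC97 knock-down replicate 1 with TTC33 knock-down replicates 2 and 3 and called 5273 genes, which points to a structure of the samples along GC content. After the correction that split called 63 genes and the real one 5115.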

How the results depend on the processing

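The GC content and length correction was chosen after the data were seen, and all other alternatives before. Scaling by DESeq2 size factors or upper-quartile factors, a filter on a mean of 5 CPM and the sum of R12 and U counts left the counts of genes past the threshold, the overlap and the number of lists within 1.5 times, where they were run, but the filter lowered the counts of genes changed at least 2-fold as given below. Testing without a filter gave 3821 genes for TTC33, 1369 for CCDC97 and an overlap of 346. DESeq2 gave 1447 for CCDC97 and an overlap of 335. Fits of the 2 groups alone gave 1339 for CCDC97 and 1479 for the direct contrast. The GC content and length correction gave 5142, 3527 and an overlap of 1327, with 12 lists for TTC33, 8 upwards and 4 downwards. WDR61 in the TTC33 knock-down turned from -0.11 to 0.0311 and PHF5A in the CCDC97 knock-down from 0.04 to -0.036 under it, neither of them called. With an estimated correlation 1 list passed for TTC33, 0 for CCDC97 and 1 for the direct contrast, and fry gave 7 for CCDC97. The cause of these shifts was not tested.

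Leaving out a library in turn gave 552 to 6512 genes for TTC33, 203 to 1981 for CCDC97, 1528 to 7767 for the direct contrast and an overlap of 36 to 594, lowest without a control replicate in the comparisons with control and highest without TTC33 knock-down replicate 1. Lists ranged from 4 to 7 for TTC33, 9 to 11 for CCDC97 and 6 to 9 for the direct contrast. TTC33 in its own knock-down ranged from -2.59 to -2.24 and CCDC97 from -1.96 to -1.94. Genes changed at least 2-fold numbered 353, 109 and 459. They ranged from 205 to 816, 66 to 169 and 299 to 919 without a library, and fell to 66, 26 and 106 under the filter on a mean of 5 CPM, which tests fewer genes. Without a filter they rose to 575 for TTC33 and 185 for CCDC97, and with the GC content and length correction to 170 for CCDC97. Of the named genes called, 41 of 64 in the TTC33 knock-down, 23 of 43 in the CCDC97 knock-down and 8 of 8 in the direct contrast passed in all 9 fits.

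Over all alternatives, the fold changes of single named genes kept their direction and side of the threshold 1990 times, lost the call 255 times, gained it 20 times and turned sign 2 times. Lists kept theirs 346 times and lost it 59 times. Whether replicate numbers pair the samples is not settled. Correlations of same-numbered deviations ran from -0.504 to 0.0936, and CCDC97 knock-down replicate 1 did not correlate best with its own number. After the GC content and length correction, same-numbered control and knock-down libraries had -0.00152 to 0.0882, and differently numbered ones -0.0651 to 0.0257. Except for control and CCDC97 knock-down replicate 1, the same-numbered pairs lay above all differently numbered ones, which points towards pairing. The replicate 1 libraries of both knock-downs had -0.193 after the correction, which points the other way. With the number as a block, 756, 240 and 1857 genes passed, the overlap was 48, and 72 genes changed at least 2-fold for CCDC97. The library with the lowest depth, CCDC97 knock-down replicate 3, held 21764203 counts. At the real sizes of all 9 libraries, edgeR recovered 36% of simulated changes of 1.5-fold in the CCDC97 comparison.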

Other observations

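The 8-base test and the choice of the single genes named here came after the results were seen.

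A pair of neighbouring genes with little expression in control cells rose in both knock-downs. NECTIN3, a cell adhesion gene, rose from 1.04 ± 0.33 CPM to 9.0 ± 2.26 with TTC33 depleted and to 4.96 ± 0.51 with CCDC97 depleted (SD, n = 3). Its antisense neighbour NECTIN3-AS1 rose from 0.14 ± 0.05 to 3.41 ± 0.33 and 2.50 ± 0.07. The log2 fold changes of NECTIN3-AS1 were 4.63 ± 0.23 and 4.18 ± 0.24 (SE), with edgeR adjusted p of 9.38e-07 and 5.87e-06. SFRP1, a secreted inhibitor of Wnt signals, fell by 1.07 and 0.77, and ULK2, a kinase of autophagy, by 0.71 and 0.77 on the log2 scale. NECTIN3 and NECTIN3-AS1 overlap on opposite strands but share no annotated exon bases. Both responses share the control libraries, which express no microRNA, so an effect of expressing any microRNA cannot be told apart from depletion. The same holds for any other difference between the control cells and the microRNA-expressing lines.

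REST targets beyond the gene list included the synaptic gene BSN, which rose by 1.75 ± 0.14 (SE) in the TTC33 knock-down, RUNDC3A by 2.96 ± 0.18, CELSR3 by 1.58 ± 0.14, the secreted neuropeptide precursor gene VGF by 1.93 ± 0.28 and the neurotrophin gene BDNF by 1.08 ± 0.18. Among the targets that did not pass were KIF1A, RAB3A and POU4F1, at 0.06, -0.14 and 0.14.

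Genes lower in each knock-down were examined for short sequences in their 3' UTRs, since an expressed microRNA can repress mRNAs that match its seed: in the CCDC97 knock-down the strongest was GAGCAGA (log2 effect -0.0564 across n = 12476 genes, Bonferroni-adjusted p = 7.49e-19), which occurs in the CCDC97 transcript, as do 17.9% of all 7-base sequences. The next 9 sequences passed as well (Bonferroni-adjusted p from 3.12e-09 to 9.98e-07, n = 12476 genes), and 8 of them do not occur in the CCDC97 transcript, so passing does not by itself point to a seed. They are not 9 separate signals, since CACTGCA and TGCAGTG, and GTGAGCC and GGCTCAC, are reverse complements of each other. GAGCAGA had a regression t of -9.91 in the CCDC97 knock-down and 0.95 in the TTC33 knock-down. Of 8-base sequences GAGCAGAA was the strongest in the CCDC97 knock-down (-0.0953, Bonferroni-adjusted p = 4.82e-23). CCCAGCTA, which also begins with 7 bases of CCDC97, passed (9.87e-12), as did TGGGAGGC and TAGCTGGG, which do not (1.54e-11 and 2.66e-11). In the TTC33 knock-down the strongest was AGCTATA (-0.0962, Bonferroni-adjusted p = 3.08e-18, n = 12476 genes), which occurs in no annotated TTC33 transcript, and by the rule set beforehand this argues against a seed that matches TTC33 over exactly these 7 bases. A shifted match stays open, since GATGAAA (-0.0615, Bonferroni-adjusted p = 6.83e-12, n = 12476 genes) and CAGCTAT, GCTATAT and AGCTATT, which each share 6 bases with AGCTATA (adjusted p = 1.41e-06, 1.22e-05 and 0.00107), passed and occur in TTC33, as do 28.0% of all 7-base sequences, and the 8-base sequences GATGAAAA, the strongest (-0.0813, adjusted p = 3.34e-10), and CAGCTATA (-0.1031, adjusted p = 7.66e-05) begin with 7 bases found there. Of the genes lower in the TTC33 knock-down 55.2% held AGCTATA or GATGAAA against 24.5% of the others. In the CCDC97 knock-down 63.8% held GAGCAGA or TAGCTGG against 34.8%, but TAGCTGG does not occur in the CCDC97 transcript. GAGCAGA alone was held by 49.7% of the genes lower there and by 19.3% of all genes in this test. These sequences were picked on the same fold changes, so a higher share among lower genes follows from that choice. The shares are not adjusted for 3' UTR length either, and they cannot decide whether off-target repression contributes. Such repression of genes lower in either knock-down stays a hypothesis, since the microRNA sequences are not given in the sources used here.

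GAGCAGA lies in CCDC97 at chromosome 19, 41319594 to 41319600 in exon 3 (coding) and 41324776 to 41324782 in exon 5 (3' UTR), plus strand. GATGAAA lies in TTC33 at chromosome 5, 40730268 to 40730274 in exon 3 (coding) and 40714850 to 40714856 in exon 5 (3' UTR), and CAGCTAT at 40716281 to 40716287 in exon 5 (coding), minus strand.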
